A study of Mus musculus with 8 samples.

How the data were processed

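The series measured gene expression in mouse lung macrophages with Affymetrix arrays. Control mice (PPARg fl/fl, C57BL/6 background) carried the loxP-flanked Pparg gene without the recombinase, and knockout mice carried CD11c-Cre as well, which deletes the flanked part of Pparg in cells that express CD11c. Cells were taken at day 2 after birth, from a gate for precursors of alveolar macrophages, and at day 11, from gates for alveolar macrophages. The day 11 gate was low in CD11b in controls and high in CD11b in knockouts. This gave 4 groups of 2 arrays, and each array held RNA of sorted cells pooled from 2 mice. Per the labels' protocols, lungs were digested with collagenase and DNase, cells were sorted by flow cytometry, and RNA was extracted with Trizol and labelled by the Affymetrix whole-transcript method.

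The deposited table holds 1 value on the log2 scale for each of 28874 probe sets and 8 arrays. The authors summarised the probe signals by RMA in R 2.15.2, per the submitters' processing notes. RMA adjusts the background, brings the arrays to a common distribution and combines the probes of a probe set. The level at which the probes were combined is not given in the sources used here. The columns share 1 distribution to within 0.026 log2 units at every rank, with a median of 5.35 on each array, so a shift of all genes between arrays cannot be seen in them. Scanner files were not used here. The number of arrays, 2 per group, limits the precision.

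Probe sets were named through the annotation table of the array platform. Of the 28874 probe sets, 21159 had a single gene symbol, 1881 had several and 5834 had no entry and stayed unnamed here. Of the 21159, 21129 matched the RefSeq gene table by Entrez identifier and 30 did not, and no symbol changed through this update. Where a gene had several probe sets, which was so for 1368 genes, the one with the highest mean over the 8 arrays was used. This left 18782 genes. Probe sets with several symbols or none entered no comparison of genes.

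Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 8 arrays, so that the groups shared 1 estimate of the spread (4 residual degrees of freedom, with 3.77 prior degrees of freedom and a prior SD of 0.081 from the empirical Bayes step). Contrasts were knockout against control at day 2 and at day 11, day 11 against day 2 in controls and in knockouts, the interaction of genotype and age, and day 11 knockout against day 2 control. Adjusted p-values are those of limma after Benjamini-Hochberg adjustment over the 18782 genes of a contrast, and a gene was called at an adjusted p under 0.05. Errors are standard errors (SE) of the log2 difference from this fit unless an SD is named. No replicate block was used, because nothing in the labels says that a replicate number marks a shared litter or day. The array means, log2 differences and list counts were drawn with matplotlib 3.10.9 in Python 3.11.15.

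Gene lists were fixed before the data were examined, as were the contrasts, the rule for named genes and the alternative settings. The 30 lists were alveolar macrophage genes, PPAR target and lipid droplet genes, fatty acid oxidation, cholesterol biosynthesis, cholesterol efflux and LXR targets, monocyte genes, macrophage genes of other tissues and lung interstitium, inflammatory cytokines and chemokines, MHC class II presentation, cell cycle, interferon response, lysosome, phagocytic and scavenger receptors, complement, GM-CSF and TGF-beta signalling, macrophage transcription factors, glycolysis, oxidative phosphorylation, tissue dissociation stress and sex-linked genes, with 10 lists of markers of other cell types, namely neutrophils, eosinophils, mast cells and basophils, dendritic cells, T and NK cells, B cells, alveolar epithelium, endothelium, fibroblasts and smooth muscle, and erythroid cells. Of 791 entries, 77 matched no gene tested, Ly6c2 among them. Some genes stand in more than 1 list. Limma's camera asks whether the genes of a list moved one way, up or down, relative to the other genes. Members that move in opposite directions cancel in it, so a list without a call may still hold many called genes. Each list was tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists of a contrast. It was tested again with a correlation estimated from the data. Fry, whose p-value asks whether the genes of a list move on balance one way without comparing them with other genes, was run beside it. Members called were counted over all genes and again adjusted over the list alone.

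Named genes follow 1 rule. For each of the first 5 contrasts it takes the 8 largest rises and 8 largest falls among called genes whose groups of arrays did not overlap (for the interaction without that condition), leaving out gene models without a proper symbol, clones, microRNA, small nucleolar RNA, olfactory, vomeronasal, immunoglobulin and T cell receptor genes. It adds up to 4 called members with the largest change from each list and, always, Pparg, Siglecf, Itgax, Itgam, Ptprc, Adgre1, Fabp4, Car4, Marco, Cd36 and Ccr2. For day 11 knockout against day 2 control it takes 5 rises and 5 falls. Where 5 or fewer members of a list moved one way, they are named too, and those outside the rule were chosen after their values were seen. Overlaps between contrasts are counts of genes called in both, beside the count that independent lists of those sizes give. For the pair of contrasts that share the day 11 control arrays, 100 simulations of unchanged groups gave the chance value, and these arrays were also split between the 2 contrasts, a choice made after the data were seen.

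The alternatives set at the same time were a fit of only the groups compared, an intensity trend with a robust prior (with statmod 1.5.0), array weights, quantile normalization once more, centring of each array on its median, leaving out genes whose highest group mean lay below the median of the table, the mean of a gene's probe sets, testing every probe set, an additional 2-fold threshold, the replicate number as a block, the estimated inter-gene correlation, and leaving out each of the 8 arrays in turn, where the lone array of a group is assumed to vary like the other groups. A covariate for the signal of Y-linked genes and the removal of the 3 arrays in which Xist or the Y-linked genes were near the floor were chosen after seeing the data. That removal leaves a single array in every group but the day 11 controls. The spread then comes from the day 11 controls alone and does not measure that of the other groups.

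The fit was tested on simulated data with 200 genes changed by known amounts, 50 at each size, among 18782 genes. For knockout against control at day 2 it called 80% of genes changed by 0.5 log2 units, 98% of those changed by 1, and 100% of those changed by 2 or 3, with 10 calls among unchanged genes. At day 11 it called 78%, 100%, 100% and 100%, with 16 such calls. Camera called the 1 list that was shifted and 0 of the 29 other lists in both simulations. Simulated arrays of all groups had the same spread for a gene, as the fit assumes. In the data the SD of the difference between replicates ran from 0.138 (day 11 controls) to 0.252 (day 2 knockouts). The rates above do not cover such unequal spreads. The simulated genes varied independently of each other. The simulations therefore do not test camera on lists whose genes vary together, such as interferon response (estimated correlation 0.931) and cell cycle (0.618).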

Results

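PPARγ is a nuclear receptor that binds fatty acid ligands and controls genes of lipid uptake, storage and breakdown. Alveolar macrophages clear surfactant from the air spaces of the lung and form in the days around birth from fetal monocytes. Lung macrophages of control and CD11c-Cre knockout mice were profiled on 8 arrays in 4 groups of 2, control and knockout at day 2 and control and knockout at day 11, each array from the pooled cells of 2 mice. The sort gates differed with age and with genotype. Day 2 cells were CD45+ F4/80+ and high in CD11c, with either intermediate Siglec-F and intermediate CD11b or low Siglec-F and high CD11b. How these 2 day 2 gates fell on the genotypes is not given here, so deletion and gate cannot be told apart at day 2 either. Day 11 cells were CD45+, high in CD11c and in autofluorescence and positive for Siglec-F, with low CD11b in controls and high CD11b in knockouts. The genes of these surface proteins (Siglecf, Itgam for CD11b, Itgax for CD11c, Ptprc for CD45 and Adgre1 for F4/80) were therefore partly set by the sort. The median signal was 5.35 on each array on the log2 scale, and the 2 arrays of a group correlated across genes with r from 0.994 to 0.998. Arrays of different groups correlated with r from 0.9675 to 0.9937, so a high r alone says little about the agreement of replicates. The p-values given here measure the spread between these pools.

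The targeted gene came first. Pparg signal was 10.9 and 11.0 in the 2 control pools at day 2, 10.6 and 10.7 in the knockouts at day 2, 11.2 and 11.1 in the controls at day 11, and 11.3 and 11.4 in the knockouts at day 11. The knockout difference in Pparg was -0.31 ± 0.08 (SE, n = 2 arrays per group, adjusted p = 0.0346) at day 2 and 0.19 ± 0.08 (adjusted p = 0.183) at day 11. The day 2 call was lost without any single array other than knockout day 2 replicate 2. Without control day 2 replicate 1 the adjusted p was 0.0632, without control day 2 replicate 2 it was 0.191, without knockout day 2 replicate 1 it was 0.16, without either day 11 control it was 0.0581, and without either day 11 knockout it was 0.052. A probe set outside the deleted part of a gene checks nothing, and where the Pparg probes lie is not given in the sources used here. The known PPARγ targets Fabp4 and Cidec separated the genotypes, each control array lying above each knockout array. Fabp4, which carries fatty acids in the cytosol, was 7.53-fold lower in knockouts at day 2 and 9.08-fold lower at day 11, and Cidec, a lipid droplet protein, was 16.3-fold and 16.2-fold lower.

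The genes behind the gates also differed with genotype. Itgam was 8.28-fold higher in the knockouts at day 2 (log2 difference 3.05 ± 0.10, adjusted p = 2.37e-06) and 22.5-fold higher at day 11 (4.49 ± 0.10, adjusted p = 8.37e-07). Siglecf was lower by a log2 difference of -2.58 ± 0.11 at day 2 and -2.02 ± 0.11 at day 11 (adjusted p = 8.7e-06 and 2.9e-05). Adgre1 was higher at day 2 (0.53 ± 0.07, adjusted p = 0.00092). Ptprc showed no call at day 2 (-0.01, adjusted p = 0.97). The remaining small differences, Itgax at both ages (0.30 and 0.29) and Adgre1 (0.29) and Ptprc (-0.27) at day 11, lost their calls when single arrays of the groups compared were left out. Itgax at day 2 had adjusted p = 0.0726 without control replicate 1, 0.0515 without control replicate 2 and 0.0605 without knockout replicate 2. At day 11 the highest values were 0.0818 for Itgax without control replicate 2 or knockout replicate 2 (0.0638 without control replicate 1) and 0.11 for Adgre1 without knockout replicate 2 (0.0999 and 0.071 without control replicates 2 and 1). For Ptprc the highest was 0.102 without control replicate 2 (0.0636 to 0.0792 without any other day 11 array).

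**Figure D1:**
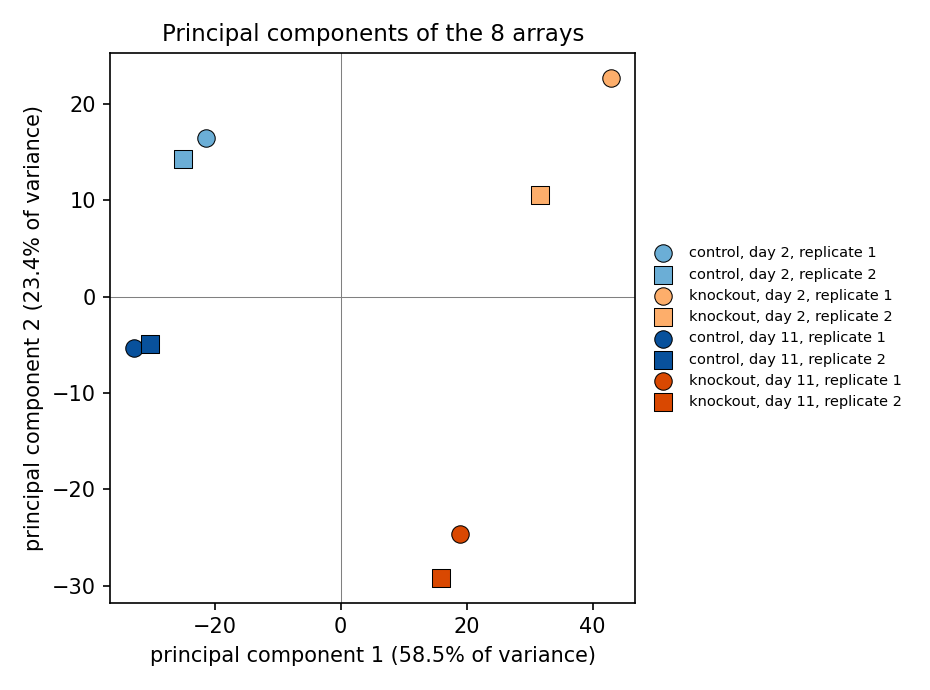
Position of the 8 arrays on the first 2 principal components of all genes tested, which hold 58.5% and 23.4% of the variance (axes in units of log2 signal). Each point is 1 array, coloured by group. The 4 control arrays lie at -21.3 to -32.7 on the first component, the day 2 knockouts at 42.9 and 31.6 and the day 11 knockouts at 18.9 and 15.9.

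**Figure D2:**
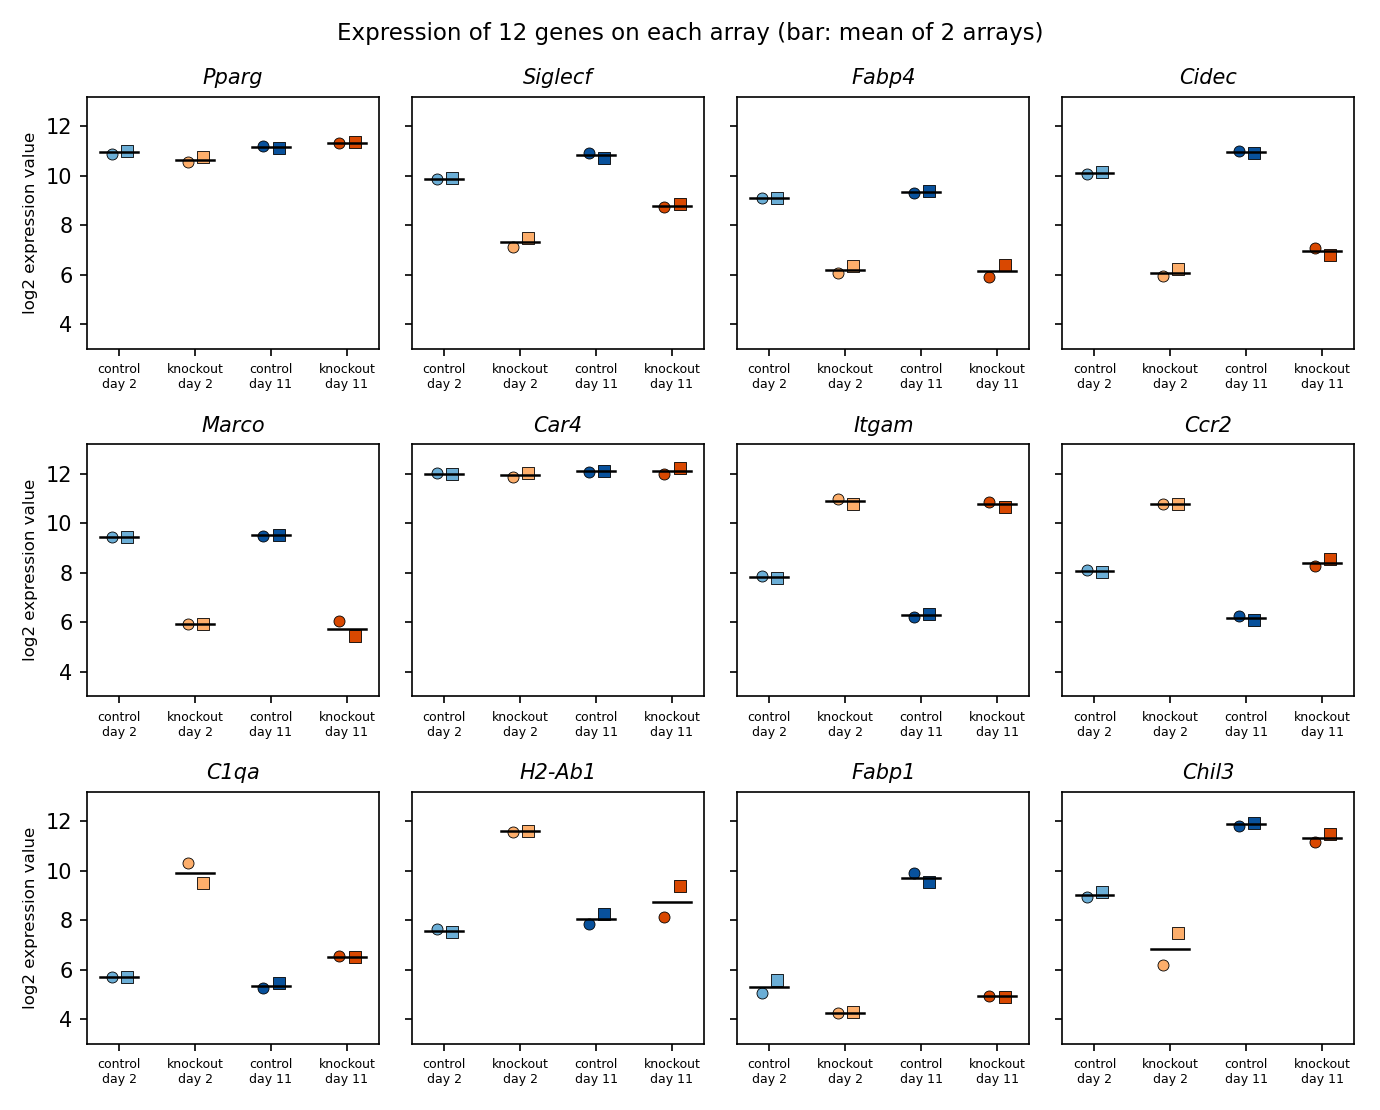
Signal of 12 genes on the log2 scale (vertical axis) in the 4 groups (horizontal axis). Each point is 1 array and each bar the mean of the 2 arrays of a group. Cidec lies at 10.1 and 11.0 in the controls and at 6.08 and 6.94 in the knockouts, while Pparg lies between 10.6 and 11.3 in all 4 groups.

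The first comparison asked how the precursor gate of knockout mice differed from that of controls 2 days after birth. Genes that mark alveolar macrophages and handle lipid were lower in the knockouts. Krt19 and Krt79, keratins expressed by alveolar macrophages, fell by 5.02 ± 0.31 and 4.25 ± 0.13 on the log2 scale (adjusted p = 3.74e-05 and 2.29e-06). The lipid droplet gene Cidec fell by 4.03 ± 0.12 (adjusted p = 2.29e-06) and the scavenger receptor gene Marco by 3.52 ± 0.16 (adjusted p = 9.48e-06). Genes of monocytes, complement and antigen presentation were higher. C1qc and C1qb, which encode chains of the complement component C1q, rose by 4.85 ± 0.13 and 4.64 ± 0.12, the anaphylatoxin receptor gene C3ar1 by 4.35 ± 0.14, and Ccr2, the receptor that draws monocytes into tissue, by 2.71 ± 0.10 (6.54-fold, adjusted p = 3.39e-06). In all, 3774 of 18782 genes were called at day 2, or 20.1%, of which 1665 were higher and 2109 lower in the knockouts. At least 2-fold differences were found for 695 of them, 484 higher and 211 lower. Among all called genes, the excess of lower ones was lost without control day 2 replicate 2. It turned around with arrays of one sex left out, a fit in which each day 2 group held a single array. The total came to 2428 without control day 2 replicate 1 and 2223 without control day 2 replicate 2. Genes given with an error from here on kept their call under every alternative tried unless stated otherwise.

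Among alveolar macrophage genes, 20 of 34 measured members fell at day 2 and 5 rose (24 fell and 5 rose when adjusted over the list alone), with a median difference of -0.52 (camera adjusted p = 3.01e-08, and adjusted p = 0.12 with an estimated correlation). Besides Krt19, Krt79, Cidec and Marco, Fabp4 fell by 2.91 ± 0.16. The 5 that rose were Itgax, Ctsk, Il1rn, Cxcl2 and Flt1, of which Itgax is a gate gene, Ctsk encodes cathepsin K, Il1rn an interleukin 1 receptor antagonist, Cxcl2 a chemokine and Flt1 a VEGF receptor. Car4, the carbonic anhydrase of mature alveolar macrophages, showed no call (-0.05, adjusted p = 0.807). Of 33 PPAR target and lipid droplet genes, 17 fell and 4 rose (19 and 5 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.000171, and adjusted p = 0.105 with an estimated correlation). Acaa1b, a peroxisomal thiolase, fell by 3.30 ± 0.19, Angptl4, a secreted inhibitor of lipoprotein lipase, by 1.87 ± 0.13, and the fatty acid transporter gene Cd36 by 0.69 ± 0.09. The 4 that rose were Pdk4, Lipe, Agpat2 and Cyp27a1, the last by 1.81 ± 0.10. Cyp27a1 encodes a mitochondrial sterol hydroxylase, Lipe a lipase, Agpat2 an acyltransferase of glycerolipid synthesis and Pdk4 a kinase that inhibits pyruvate dehydrogenase.

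Lipid breakdown and sterol synthesis moved with these genes. Of 23 fatty acid oxidation genes, 15 fell and 1, Slc25a20, rose (16 and 2 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 8.82e-08, and adjusted p = 0.125 with an estimated correlation). Ehhadh fell by 1.14 ± 0.14, Cpt2, which releases acyl groups from carnitine in the mitochondrion, by 1.08 ± 0.07, Ech1 by 1.05 ± 0.17 and Acadl by 0.97 ± 0.06. Of 19 cholesterol biosynthesis genes, 8 fell and none rose (13 fell adjusted over the list alone), with a median of -0.41 (camera adjusted p = 6.72e-05, and adjusted p = 0.265 with an estimated correlation), among them Hmgcs1 by 1.30 ± 0.12 and Lss by 0.62 ± 0.10. Of 15 cholesterol efflux and LXR target genes, 7 fell and 3 rose (7 and 5 adjusted over the list alone) and the list was not called (camera adjusted p = 0.759), its median of -0.08 and mean of 0.04 having opposite signs. Nr1h3, which encodes the oxysterol receptor LXRα, fell by 1.63 ± 0.23 and Apoc2 rose by 1.25 ± 0.11. The 2 others that rose were Cyp27a1 and Apoe. Apoe (0.98 ± 0.20) lost its call without control day 2 replicate 1 (adjusted p = 0.0572), control day 2 replicate 2 (0.081) or knockout day 2 replicate 1 (0.056).

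Cell cycle genes were lower in the knockouts at day 2 almost throughout. Of 42 measured, 39 fell and 1 rose (40 and 1 adjusted over the list alone), with a median of -0.77 (camera adjusted p = 8.05e-19, and adjusted p = 0.169 with an estimated correlation). Kif23, a kinesin needed to complete cell division, fell by 1.28 ± 0.13, and the spindle checkpoint gene Bub1b by 1.02 ± 0.07. The single member that rose was Ccnd1, cyclin D1, which acts early in the cycle downstream of growth factors (1.86 ± 0.15). Of 38 oxidative phosphorylation genes, 6 fell, Ndufa4 by 0.67 ± 0.08, and none rose (2 fell adjusted over the list alone, camera adjusted p = 0.000684, and adjusted p = 0.227 with an estimated correlation). Of 23 glycolysis genes, 7 rose and 2 fell, the latter being Egln3 (-1.83 ± 0.15) and Pdk1 (-1.12 ± 0.08), both genes induced at low oxygen (7 and 2 adjusted over the list alone). Slc16a3, a lactate exporter, rose by 1.16 ± 0.09. The glycolysis call (camera adjusted p = 0.0186, and adjusted p = 0.38 with an estimated correlation) was lost without knockout day 2 replicate 1 (median 0.10, adjusted p = 0.308).

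Monocyte genes rose together. Of 27 measured, 22 rose and none fell (23 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 2.2e-19, and adjusted p = 0.044 with an estimated correlation), and no other list kept its call at day 2 with an estimated correlation. Ifitm3 and Ifitm6, membrane proteins induced by interferon, rose by 3.78 ± 0.44 and 3.62 ± 0.07, and Cx3cr1, the fractalkine receptor, by 3.46 ± 0.13. Of 12 genes of MHC class II presentation, 10 rose and none fell (10 adjusted over the list alone), with a median of 1.66 (camera adjusted p = 5.35e-11, and adjusted p = 0.0876 with an estimated correlation). H2-Ab1 rose by 4.01 ± 0.35, H2-Aa by 3.76 ± 0.30, H2-Eb1 by 3.70 ± 0.36 and the invariant chain gene Cd74 by 3.50 ± 0.28. Dendritic cell markers moved with them, 12 of 19 rising and none falling (13 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 5.35e-11, and adjusted p = 0.0958 with an estimated correlation). The transcription factor gene Irf4 rose by 4.04 ± 0.30 and the lectin genes Cd209a and Clec9a by 3.81 ± 0.27 and 2.49 ± 0.18. Of 32 macrophage genes of other tissues and lung interstitium, 14 rose and 2, Mertk and Cbr2, fell (14 and 2 adjusted over the list alone, camera adjusted p = 2.21e-06, and adjusted p = 0.0876 with an estimated correlation). The transcription factor gene Maf rose by 2.39 ± 0.26 and the scavenger receptor gene Stab1 by 2.53 ± 0.32.

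Regulators of macrophage fate moved in both directions. Of 32 macrophage transcription factors, 11 rose and 8 fell (12 and 8 adjusted over the list alone), Runx3 by 3.24 ± 0.12 beside Irf4 and Maf, while Nr1h3, Cebpa, Cebpb, Spi1 and Bhlhe41 were among those that fell. The list's call (camera adjusted p = 0.0188, and adjusted p = 0.161 with an estimated correlation) was lost without knockout day 2 replicate 2 (adjusted p = 0.0769). Of 26 genes of GM-CSF and TGF-β signalling, the cytokines that drive alveolar macrophage development, 12 rose and 4 fell (14 and 5 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.00146, and adjusted p = 0.0876 with an estimated correlation). Those that rose include feedback inhibitors of both pathways, Socs3 (1.91 ± 0.20), Cish (1.15 ± 0.09) and Smad7 (1.19 ± 0.13), and the TGF-β effector gene Smad3 (1.51 ± 0.07). The 4 that fell were the transcription factor genes Spi1, Cebpa, Cebpb and Bhlhe41.

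Inflammatory cytokines and chemokines were higher at day 2, 25 of 39 members having risen and none fallen (28 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 2.15e-15, and adjusted p = 0.0876 with an estimated correlation). The monocyte attractants Ccl2 and Ccl7 rose by 3.80 ± 0.23 and 2.87 ± 0.37, and Ptgs2, the inducible cyclooxygenase, by 3.18 ± 0.16. Genes induced by tissue dissociation moved the same way, 10 of 20 having risen and none fallen (12 and 2 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 7.16e-06, and adjusted p = 0.0876 with an estimated correlation). Egr3 rose by 1.38 ± 0.14 and Junb by 0.66 ± 0.08. Of 30 phagocytic and scavenger receptor genes, 17 rose and 8 fell (18 and 8 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.000306, and adjusted p = 0.0958 with an estimated correlation). Fcgr2b, the inhibitory Fc receptor, rose by 1.88 ± 0.07 and the lectin gene Clec4d by 1.68 ± 0.13, while Marco and Cd36 fell as given above. Of 18 complement genes, 7 rose and none fell (7 adjusted over the list alone, camera adjusted p = 2.22e-05, and adjusted p = 0.0876 with an estimated correlation), C1qa, C1qb, C1qc and C3ar1 among them. The 2 gate genes Itgam and Itgax belong to that list as well. Of 39 lysosome genes, 6 fell and 4 rose (8 and 4 adjusted over the list alone), the 4 being Ctsh (0.69 ± 0.07), Lgmn (0.54 ± 0.06), Ctsk (0.52 ± 0.07) and Man2b1, and the list was not called (camera adjusted p = 0.746).

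Interferon response genes separated the 2 day 2 knockout pools from each other. The median signal of the 33 genes was 9.09 in knockout day 2 replicate 1 and 6.99 in replicate 2, against 6.36 and 5.93 in the controls of that age, 5.93 and 5.81 in the day 11 controls and 6.53 and 6.01 in the day 11 knockouts. With both pools, the list median difference at day 2 was 1.40 (camera adjusted p = 5.9e-09, and adjusted p = 0.376 with an estimated correlation), and it was 0.45 without replicate 1 and 2.44 without replicate 2. The genes called were 5, all higher, namely Ifi205, Oas2, Mx2, Ly6e and Trim30a (3 adjusted over the list alone). Ifi205, an interferon-inducible gene, was 4.84 ± 0.82 higher, a call lost with a trend and robust prior (adjusted p = 0.0545) and kept in the other settings. Calls lost without single arrays were those of Trim30a (7 of the 8 arrays, adjusted p from 0.0578 to 0.186), Oas2 (6 arrays, 0.0649 to 0.164) and Mx2 (either day 2 control, 0.0849 and 0.102). Replicate 1 also carried part of the median of complement genes, which was 0.23 with both pools, 0.04 without replicate 1 and 0.55 without replicate 2, and of inflammatory genes, 0.97 with both and 0.65 without replicate 1. Without that pool the median was 0.86 for monocyte genes, 1.64 for MHC class II genes and 0.73 for dendritic cell markers.

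**Figure D3:**
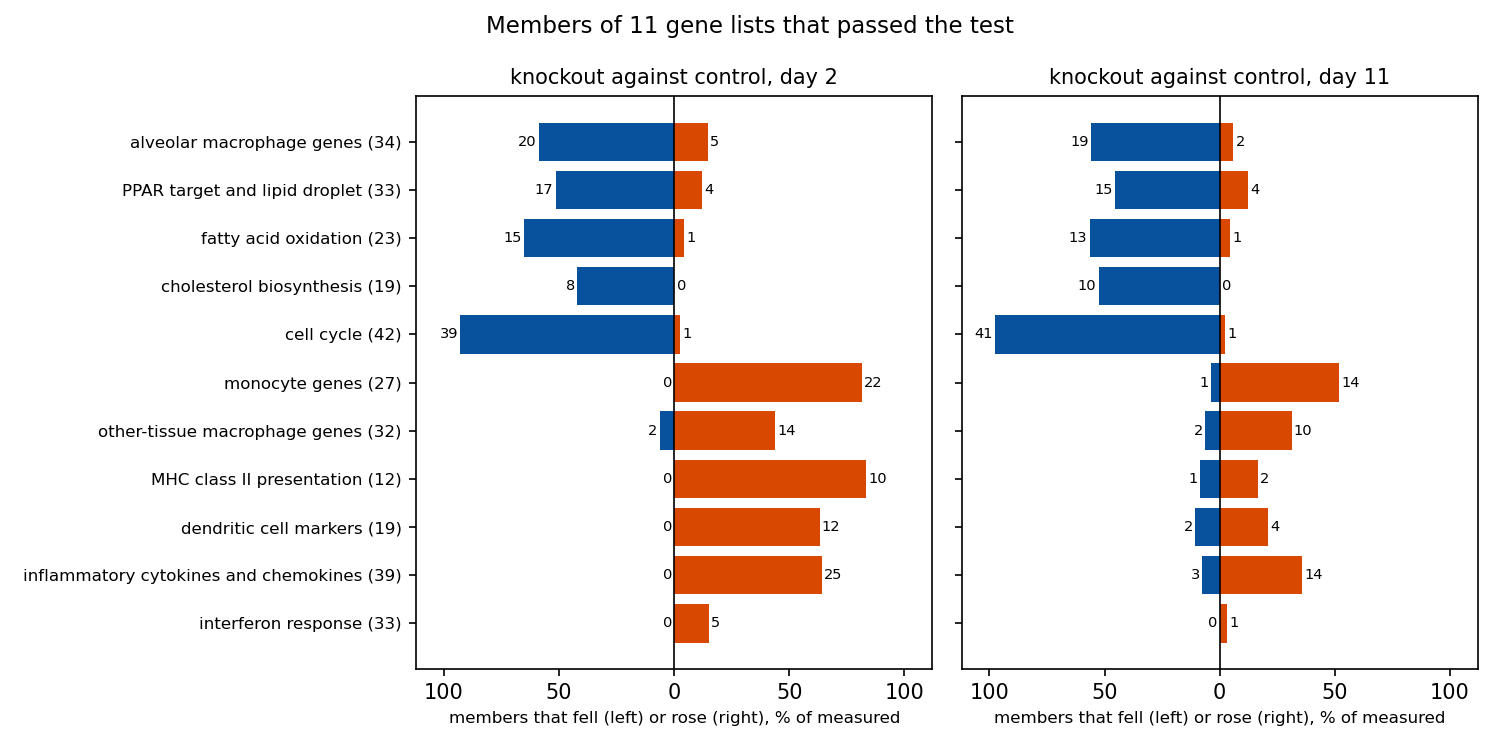
Percent of measured members of 11 gene lists (vertical axis) that were called higher (right) or lower (left) in knockouts, at day 2 and at day 11 (panels), with the number of genes beside each bar. Cell cycle genes fell in 39 of 42 cases at day 2 and 41 of 42 at day 11, and MHC class II genes rose in 10 of 12 cases at day 2 and 2 of 12 at day 11.

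**Figure D4:**
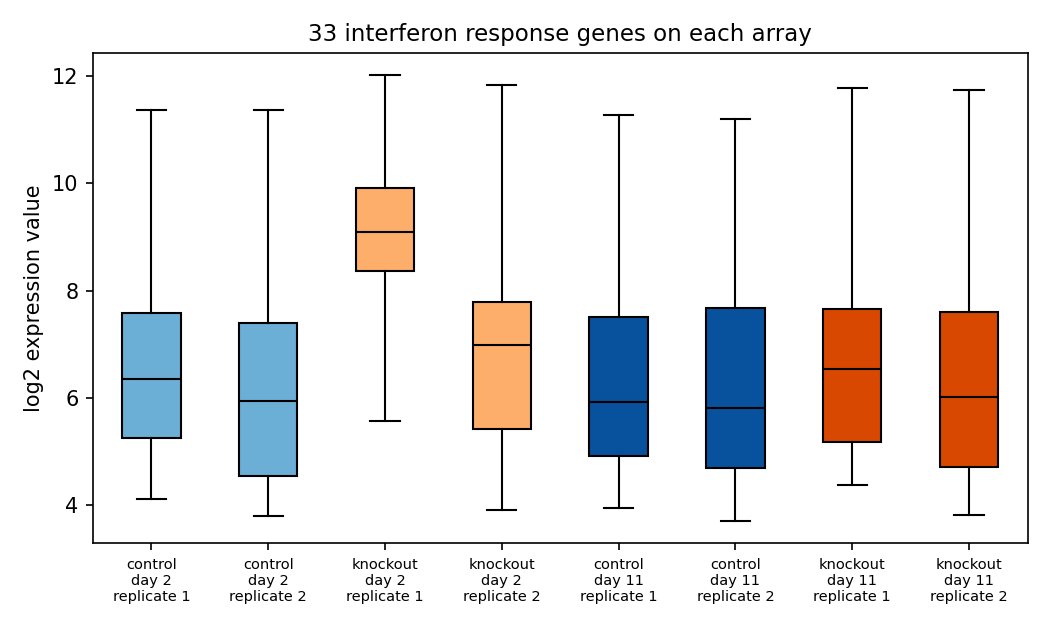
Signal of the 33 interferon response genes on the log2 scale (vertical axis) on each of the 8 arrays (horizontal axis). Boxes span the quartiles with the median as a line and whiskers reach the lowest and highest gene. The median is 9.09 in knockout day 2 replicate 1 and lies between 5.81 and 6.99 on the 7 other arrays.

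Markers of other cell types at day 2 moved unevenly. Of 17 neutrophil markers, 9 rose and 2, the chemokine receptor genes Cxcr1 (-2.82 ± 0.16) and Cxcr2, fell (10 and 2 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 0.000131, and adjusted p = 0.0876 with an estimated correlation). Mmp8, a neutrophil collagenase, rose by 4.40 ± 0.14 and Retnlg by 2.50 ± 0.11. Of 22 endothelial markers, 7 rose and 1, Plvap, fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00418, and adjusted p = 0.161 with an estimated correlation), Pecam1 by 1.68 ± 0.10 and Eng by 1.56 ± 0.14. Of 21 T and NK cell markers, 4 rose, Il7r by 2.82 ± 0.32 and Cd3e, Cd5 and Klrk1 by less, and none fell (4 adjusted over the list alone, camera adjusted p = 0.0109, and adjusted p = 0.105 with an estimated correlation). Il7r, the interleukin 7 receptor, is also made by fetal monocytes. Of 25 alveolar epithelial markers, 5 rose (Pdpn by 3.04 ± 0.24, Napsa, Lyz1, Hopx and Etv5) and 3 fell (Ager, Rtkn2 and Scgb1a1, the last by 1.05 ± 0.18), and the list was not called (5 and 4 adjusted over the list alone, camera adjusted p = 0.319). Pdpn and Lyz1 are also expressed by macrophages. Of 14 B cell markers, 1 rose, Bank1, by 1.64 ± 0.09 (1 adjusted over the list alone). The list's call (camera adjusted p = 0.0326, and adjusted p = 0.227 with an estimated correlation) was lost without control day 2 replicate 2 (adjusted p = 0.156) or knockout day 2 replicate 2 (adjusted p = 0.0842). Of 12 mast cell and basophil markers, Cpa3 and Hdc rose (2 adjusted over the list alone). That call (camera adjusted p = 0.0291, and adjusted p = 0.155 with an estimated correlation) was lost without control day 2 replicate 1 (adjusted p = 0.0876) or knockout day 2 replicate 1 (adjusted p = 0.1). In 4 further lists few or no genes were called and no list was called. They were eosinophil markers (Ear6 lower by -0.52 ± 0.06, camera adjusted p = 0.821), fibroblast and smooth muscle markers (Gpx3 higher by 0.97 ± 0.12 and Sparc lower, camera adjusted p = 0.641), erythroid markers (Epor and Car1 lower, camera adjusted p = 0.961) and sex-linked genes (0 of 4 called, camera adjusted p = 0.821). Their counts were the same when adjusted over the list alone. The sex-linked genes differed by -1.717 to 3.354 without a call. Pools of 1 group also differed in them, Xist being 10.44 and 3.38 in the 2 day 2 controls. Among the genes of these lists, calls lost without single arrays were those of Cpa3 (6 arrays, adjusted p from 0.0589 to 0.207), Cd5 (3 arrays, 0.0767 to 0.142), Klrk1 (either day 2 control, 0.113), Hdc and Car1 (control day 2 replicate 1, 0.0523 and 0.0615) and Sparc (control day 2 replicate 2, 0.0513).

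At day 11 the question was how the CD11b-high cells of knockout mice differed from the CD11b-low cells of controls. Krt79 fell by 5.33 ± 0.13 on the log2 scale (adjusted p = 1.1e-06), Fabp1, a fatty acid binding protein, by 4.80 ± 0.16 (adjusted p = 4.53e-06), Cidec by 4.02 ± 0.12 (adjusted p = 2.22e-06) and Marco by 3.77 ± 0.16 (adjusted p = 1.09e-05). Beside the gate gene Itgam, Hpse, heparanase, rose by 4.98 ± 0.49 (adjusted p = 0.000321), C3ar1 by 4.96 ± 0.14 (adjusted p = 1.64e-06) and Ecm1, an extracellular matrix protein, by 4.49 ± 0.09 (adjusted p = 8.37e-07). Other genes that rose more than 16-fold were Papss2, which makes the sulfate donor of the cell (4.45 ± 0.13), and the carbonic anhydrase gene Car6 (4.29 ± 0.13). The growth factor gene Csf1 rose by 2.87 ± 0.08. Of 18782 genes, 3500 were called, or 18.6%, with 1755 higher and 1745 lower in the knockouts, and 648 differed at least 2-fold, 348 higher and 300 lower. The total was 2059 without control day 11 replicate 1.

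Of the 34 alveolar macrophage genes, 19 fell and 2, Itgax and Ctsk (0.63 ± 0.07), rose at day 11 (the same numbers adjusted over the list alone), with a median of -0.49 (camera adjusted p = 1.94e-08, and adjusted p = 0.276 with an estimated correlation). Fabp4 fell by 3.18 ± 0.16 and Krt19 by 3.88 ± 0.31. Of the 33 PPAR target and lipid droplet genes, 15 fell and 4 rose (the same numbers adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.000543, and adjusted p = 0.276 with an estimated correlation). Acaa1b fell by 3.88 ± 0.19 and Ucp3, a mitochondrial uncoupling protein, by 1.95 ± 0.18, and the 4 that rose were Cyp27a1 (0.87 ± 0.10), Lipe, Agpat2 and Hilpda, the last a lipid droplet protein that inhibits lipolysis. Cd36 was lower by -0.32 ± 0.09 (adjusted p = 0.0397), a call lost without either day 2 control (adjusted p = 0.0621), control day 11 replicate 1 (0.136) or replicate 2 (0.16) or knockout day 11 replicate 2 (-0.195 on the log2 scale, adjusted p = 0.189). Fatty acid oxidation genes fell in 13 of 23 cases and 1, Hadh, rose (15 and 4 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 9.53e-05, and adjusted p = 0.368 with an estimated correlation), Hsd17b4 by 1.42 ± 0.07 and Acaa1a by 0.93 ± 0.10. Cholesterol biosynthesis genes fell in 10 of 19 cases and none rose (12 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 9.53e-05, and adjusted p = 0.368 with an estimated correlation), Hmgcs1 by 1.11 ± 0.12 and Sqle by 0.99 ± 0.13. Of the cholesterol efflux and LXR targets, 4 rose (Apoe by 2.01 ± 0.20, Apoc2 by 1.39 ± 0.11, Npc1 and Cyp27a1) and 4 fell (Nr1h3 by 1.87 ± 0.23, Abcg1, Scarb1 and Nceh1). The list was not called (5 and 5 adjusted over the list alone, camera adjusted p = 0.761).

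All but 1 of the cell cycle genes were lower at day 11. Of 42, 41 fell and Ccnd1 rose by 2.33 ± 0.15 (the same numbers adjusted over the list alone), with a median of -1.09 (camera adjusted p = 7.09e-30, and adjusted p = 0.276 with an estimated correlation). Kif23 fell by 1.75 ± 0.13, Bub1 by 1.60 ± 0.10 and Stmn1, a microtubule regulator, by 1.60 ± 0.19. Monocyte genes rose in 14 of 27 cases and 1, Spn, fell (15 and 1 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 2.32e-08, and adjusted p = 0.231 with an estimated correlation). Thbs1 rose by 2.44 ± 0.21, Ccr2 by 2.26 ± 0.10 and Itga4 by 1.49 ± 0.09. Inflammatory genes rose in 14 of 39 cases and 3 fell (the same numbers adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.000204, and adjusted p = 0.368 with an estimated correlation). Ptgs2 rose by 3.03 ± 0.16 and Socs3, an inhibitor of cytokine signalling, by 2.73 ± 0.20, whereas the 3 that fell were the chemokine genes Ccl17 (-2.19 ± 0.26), Ccl22 and Ccl9. Dissociation-induced genes rose in 9 of 20 cases and 1, Jun, fell (10 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.00439, and adjusted p = 0.276 with an estimated correlation), Egr3 by 1.23 ± 0.14. Lysosome genes rose in 12 of 39 cases and 2, Arsb and Pla2g15, fell (13 and 5 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.00288, and adjusted p = 0.276 with an estimated correlation), Ctsk and Lgmn (0.62 ± 0.06) among those higher. C1qb and C1qc rose by 2.45 ± 0.12 and 2.00 ± 0.13 within a complement list in which 6 of 18 rose and the receptor genes C5ar1 and C5ar2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00915, and adjusted p = 0.276 with an estimated correlation). The call of the complement list was also lost with arrays of one sex left out.

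Antigen presentation genes were mostly without a call at day 11. Of 12, 2 rose, the costimulatory genes Cd86 (1.70 ± 0.10) and Cd80 (0.69 ± 0.08), and H2-Oa fell by 1.31 ± 0.10 (the same numbers adjusted over the list alone). The call of that list (camera adjusted p = 0.0343, and adjusted p = 0.462 with an estimated correlation) was lost without control day 11 replicate 1 (adjusted p = 0.0677) or knockout day 11 replicate 2 (adjusted p = 0.234). Of 19 dendritic cell markers, 4 rose (Clec9a by 3.05 ± 0.18, Irf4 by 1.93 ± 0.30, Cd24a by 1.26 ± 0.10 and Epsti1) and Ccl17 and Ccl22 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.706). Of the interferon genes, 1 of 33 rose, Ly6e by 0.53 ± 0.08 (1 adjusted over the list alone, camera adjusted p = 0.438). The shared estimate of the spread includes the difference between the 2 day 2 knockout pools in these genes (median 1.988). That widens the errors at day 11, where differences reached 1.396 without a call. The number of calls is therefore no measure of an unchanged response. Of 17 neutrophil markers, 2 rose (Mmp8 by 3.23 ± 0.14 and S100a8 by 1.33 ± 0.15) and 2 fell (Cxcr1 by 1.54 ± 0.16 and Cxcr2), without a call of the list (camera adjusted p = 0.761). Among phagocytic and scavenger receptors 13 of 30 rose and 9 fell (14 and 9 adjusted over the list alone), also without a call of the list (camera adjusted p = 0.0907). Mfge8, which bridges phagocytes to dying cells, rose by 2.80 ± 0.13 and the collectin receptor gene Colec12 by 2.01 ± 0.13, and the Fc receptor gene Fcgr4 fell by 2.20 ± 0.31.

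The genotype differences at the 2 ages shared many genes. Called in both with the same sign were 2056 genes, 922 higher and 1134 lower in knockouts, against 352 for independent lists of these sizes, and 45 were called in both with opposite signs, against 352. The log2 differences at the 2 ages correlated across genes with r = 0.716 (Spearman 0.540), genes not being independent replicates. The 2 comparisons had no array in common. In both, knockouts had higher Itgam and lower Siglecf, genes partly set by the sort. Deletion and differences in the cells sorted were therefore not told apart in this overlap. At least 2-fold at both ages were 363 genes.

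In controls, the change from day 2 to day 11 compared cells of the precursor gate with those of the CD11b-low day 11 gate. Age and gate therefore changed together. Fbp1, fructose-1,6-bisphosphatase of gluconeogenesis, rose by 5.82 ± 0.46 on the log2 scale (adjusted p = 0.000682), Rnase2a, a ribonuclease of the eosinophil-associated family, by 4.41 ± 0.43 and Fabp1 by 4.40 ± 0.16 (adjusted p = 5.81e-05). The lipase gene Lipf rose by 3.44 ± 0.25, Pdk4 by 2.96 ± 0.18 and Ch25h, cholesterol 25-hydroxylase, by 2.75 ± 0.19. Thbs1 fell by 2.70 ± 0.21, Car6 by 2.56 ± 0.13, Ecm1 by 2.04 ± 0.09, Ccr2 by 1.92 ± 0.10 (adjusted p = 0.000158) and the gate gene Itgam by 1.56 ± 0.10. Of 18782 genes, 996 were called, or 5.3%, 528 rising and 468 falling, with 148 at least 2-fold (86 rising and 62 falling). This total rests on few arrays, since it was 233 without control day 2 replicate 1, 268 without replicate 2 of that group, 251 without control day 11 replicate 1 and 346 without replicate 2.

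Of the 34 alveolar macrophage genes, 11 rose and none fell with age in controls (15 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 4.22e-10, and adjusted p = 0.562 with an estimated correlation). Kcnip4 rose by 1.81 ± 0.14, Krt79 by 1.14 ± 0.13 and the adhesion molecule gene Epcam by 0.80 ± 0.08. Chil3, a chitinase-like protein of alveolar macrophages (2.85 ± 0.35), and Siglecf (0.94 ± 0.11) lost their calls without control day 2 replicate 1 (adjusted p = 0.0548 and 0.0525). Marco (0.06), Fabp4 (0.22) and Car4 (0.09) were not called. Of the PPAR target and lipid droplet genes, 4 rose (Pdk4, Ucp3 by 2.74 ± 0.18, Cidec and Acot1) and Dgat2 fell (7 and 2 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00669, and adjusted p = 0.562 with an estimated correlation). Cell cycle genes fell in 6 of 42 cases and none rose (19 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 4.22e-10, and adjusted p = 0.562 with an estimated correlation). Of the 27 monocyte genes 8 fell and 2, Nr4a1 and Spn, rose (9 and 2 adjusted over the list alone). The call (camera adjusted p = 0.0301, and adjusted p = 0.562 with an estimated correlation) was lost without control day 2 replicate 1 (adjusted p = 0.0553) or control day 11 replicate 1 (adjusted p = 0.0776). Calls lost without single arrays were those of Cidec (any control array, adjusted p from 0.0522 to 0.083), Nr4a1 (4 arrays, 0.0853 to 0.175) and Acot1 (6 arrays, 0.053 to 0.211). Apolipoprotein C2, Apoc2, fell by 1.19 ± 0.11 and C3ar1 by 1.40 ± 0.14.

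The step of age and gate in knockouts, whose day 11 gate was high in CD11b, brought larger falls. Clec4a1, a lectin-like receptor, fell by 4.33 ± 0.16 on the log2 scale (20.1-fold, adjusted p = 9.96e-06), Adgre4, an adhesion receptor related to F4/80, by 3.84 ± 0.09 and Ifitm3 by 3.77 ± 0.44. Cd209a fell by 3.72 ± 0.27, the sorting receptor gene Sorl1 by 3.61 ± 0.11, C1qa by 3.38 ± 0.21 and Ccr2 by 2.38 ± 0.10. Chil3 rose by 4.48 ± 0.35 (22.3-fold, adjusted p = 0.000253), Fbp1 by 3.78 ± 0.46, Rnase2a by 3.54 ± 0.43, Ephx1, epoxide hydrolase, by 2.94 ± 0.18, Pdk4 by 2.78 ± 0.18, the gate gene Siglecf by 1.49 ± 0.11 and the Pparg signal by 0.70 ± 0.08 (adjusted p = 0.00167). Marco (-0.19), Fabp4 (-0.05), Car4 (0.16) and Itgam (-0.12) were not called. Of 18782 genes, 2915 were called, or 15.5%, 1655 rising and 1260 falling, and of the 370 that changed at least 2-fold 116 rose and 254 fell. With only the 2 groups of a comparison fitted, fewer genes were called with age in knockouts than in controls. The SD of the difference between replicates was 0.252 and 0.192 in knockouts at days 2 and 11 and 0.157 and 0.138 in controls. The 2915 rests on 1 spread shared by all groups. The total was 1632 without knockout day 2 replicate 1 and 1541 without knockout day 11 replicate 2.

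In knockouts 17 of 34 alveolar macrophage genes rose with age and 2, Tgm2 and Epcam, fell (19 and 2 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 4.89e-07, and adjusted p = 0.24 with an estimated correlation). Monocyte genes fell in 16 of 27 cases and none rose (16 and 3 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 8.87e-10, and adjusted p = 0.166 with an estimated correlation), where Plac8 decreased by 3.50 ± 0.27 and Cx3cr1 decreased by 2.89 ± 0.13. MHC class II genes fell in 9 of 12 cases and none rose (9 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 2.13e-08, and adjusted p = 0.24 with an estimated correlation), H2-Ab1 by 2.84 ± 0.35 and Cd74 by 2.27 ± 0.28. Dendritic cell markers fell in 9 of 19 cases and Clec9a rose by 1.90 ± 0.18 (10 and 1 adjusted over the list alone, camera adjusted p = 2.92e-06, and adjusted p = 0.246 with an estimated correlation). Neutrophil markers fell in 9 of 17 cases and Cxcr1 rose (10 and 2 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.000266, and adjusted p = 0.24 with an estimated correlation), Ngp by 2.21 ± 0.18. Cell cycle genes fell in 32 of 42 cases (38 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 6.39e-22, and adjusted p = 0.246 with an estimated correlation), Uhrf1 by 1.14 ± 0.11 and Bub1 by 1.03 ± 0.10. Interferon genes fell in 5 of 33 cases, Ifi205, Oas2, Mx2, Rtp4 and Ifi27l2a (5 adjusted over the list alone), and their median of -1.67 (camera adjusted p = 9.07e-08, and adjusted p = 0.455 with an estimated correlation) was -0.27 without knockout day 2 replicate 1 and -2.70 without replicate 2. Calls lost without single arrays were those of Rtp4 (6 arrays, adjusted p from 0.0633 to 0.159), Oas2 (either day 11 knockout, 0.0591 and 0.0666) and Ifi205 (knockout day 11 replicate 2, 0.0973).

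The age changes of the 2 genotypes overlapped in 511 genes called with the same sign, 283 rising and 228 falling, against 77.9 for independent lists, and 35 with opposite signs, against 76.7. The correlation across genes was r = 0.452, and the comparisons had no array in common. The 511 were 136 without control day 2 replicate 1, 158 without control day 2 replicate 2, 147 without control day 11 replicate 1 and 205 without control day 11 replicate 2.

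Whether the difference between knockouts and controls changed between the ages was tested as an interaction. The day 11 gates differed with genotype, and whether those of day 2 did is not given here. Deletion and gate therefore cannot be told apart in this term. Several of the most negative terms came from genes raised in knockouts at day 2 and near the control level at day 11. Ifitm6 was 3.96 in controls and 7.58 in knockouts at day 2 and 4.12 in both at day 11 (interaction -3.62 ± 0.10, adjusted p = 1.52e-05). Cd209a was 5.42 and 9.22 at day 2 and 5.28 and 5.50 at day 11 (-3.59 ± 0.38, adjusted p = 0.00336), and Runx3, a transcription factor, was 6.02 and 9.25, then 5.78 and 6.10 (-2.91 ± 0.16). Fabp1 took another course, since it rose with age in controls from 5.31 to 9.71 and stayed at 4.27 and 4.92 in knockouts (-3.75 ± 0.23, adjusted p = 0.000399). Ccl17 was 8.58 in controls and 9.74 in knockouts at day 2 and 10.7 and 8.50 at day 11 (-3.35 ± 0.37). The 3 largest positive terms came from genes that fell with age in controls and not in knockouts. Fstl1, follistatin-like 1, went from 8.98 to 7.20 in controls and from 9.13 to 10.5 in knockouts (3.15 ± 0.26, adjusted p = 0.00115). Car6 went from 7.58 to 5.02 and from 9.18 to 9.31 (2.69 ± 0.18) and Ecm1 from 8.32 to 6.28 and from 10.3 to 10.8 (2.47 ± 0.13). The gate gene Itgam had a term of 1.44 ± 0.14. In all 615 genes were called, or 3.27%, 242 positive and 373 negative, and of the 232 with a term of at least 2-fold 179 were negative.

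Among the lists, MHC class II genes had a negative interaction term in 8 of 12 cases and none was positive (10 adjusted over the list alone), with a median of -1.15 (camera adjusted p = 1.97e-13, and adjusted p = 0.173 with an estimated correlation). The terms of H2-Ab1, H2-Aa and Cd74 (-3.29, -2.95 and -2.77) lost their calls without control day 2 replicate 1 (adjusted p = 0.0694, 0.0653 and 0.0662), control day 2 replicate 2 (0.0744, 0.0643 and 0.0689) or control day 11 replicate 2 (0.0672, 0.0585 and 0.0607). Dendritic cell markers were negative in 8 of 19 cases and positive in 1, Cd24a (10 and 1 adjusted over the list alone), with a median of -0.99 (camera adjusted p = 2.28e-09, and adjusted p = 0.233 with an estimated correlation). Of the monocyte genes 6 of 27 were negative, Plac8 at -3.27 ± 0.39, and 2, Emilin2 and the gate gene Itgam, positive (13 and 4 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 1.23e-05, and adjusted p = 0.173 with an estimated correlation). C1qa, C1qc and C1qb had terms of -3.03 ± 0.30, -2.84 ± 0.18 and -2.19 ± 0.17. Among alveolar macrophage genes Bhlhe41 and Serpinb1a were positive and Fabp1, Krt79 and Epcam negative (6 and 6 adjusted over the list alone), the calls of Krt79 (4 arrays, adjusted p from 0.0553 to 0.105) and Serpinb1a (6 arrays, 0.065 to 0.17) being lost without single arrays. No difference between the ages was detected in that list as a whole (camera adjusted p = 0.912) or in PPAR target genes (0 positive and 2 negative, 4 and 3 adjusted over the list alone, camera adjusted p = 0.923). The number of genes called was 197 without control day 2 replicate 1, 215 without control day 2 replicate 2, 254 without control day 11 replicate 1, 248 without control day 11 replicate 2, 405 without knockout day 11 replicate 2 and 942 without knockout day 2 replicate 2.

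The last comparisons asked how far the knockout cells of day 11 resembled the precursor stage of controls. Of the genes called in controls with age, 364 were called in the opposite direction in the day 11 knockouts, 184 that rose with age and were low in knockouts and 180 that fell with age and were high, or 34.8% of the rises and 38.5% of the falls. Another 185 were called in the same direction, and independent lists give 92.8 for each. Both comparisons use the day 11 control arrays, which alone produced r = -0.503 across genes in 100 simulations of unchanged groups (0.03 genes called with opposite signs on average), against r = -0.235 observed. The covariance was -0.0243, against -0.0062 simulated, a difference of -0.0181. The 2 control arrays were then split between the comparisons, a test chosen after the data were seen. With replicate 1 serving age and replicate 2 genotype, 145 genes were called with opposite signs, against 19 for independent lists, and 49 with the same sign, against 18.9 (r = -0.199, covariance -0.0216). The reverse gave 113 against 16.1 and 47 against 15.8 (r = -0.161, covariance -0.0175). Without a shared array both directions exceeded independent lists, the opposite one by more. The 364 fell to 106 without control day 2 replicate 1, 133 without control day 2 replicate 2, 117 without control day 11 replicate 1 and 175 without control day 11 replicate 2. Set directly against day 2 controls, day 11 knockouts differed in 4813 genes (25.6%, 2356 higher and 2457 lower), 3018 without control day 2 replicate 1 and 2948 without replicate 2. Krt79 was lower by -4.19 ± 0.13, Marco by -3.71 ± 0.16 and the transporter gene Slco2b1 by -3.64 ± 0.30, and Mmp8 was higher by 4.84 ± 0.14, Hpse by 4.67 ± 0.49, Clec9a by 4.39 ± 0.18, Ch25h by 4.33 ± 0.19 and Rnase2a by 4.29 ± 0.43. The root mean square distance between group means over all genes was 0.43 from day 11 knockouts to day 2 controls, 0.42 from day 11 knockouts to day 11 controls, 0.36 between the knockouts of the 2 ages and 0.25 between the controls of the 2 ages.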

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

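All tests of explanations in this part were chosen after the result was seen, while the interaction of genotype and age was planned. A change between the ages in the difference between knockouts and controls was found by the interaction term, for 615 genes. Deletion and gate cannot be told apart in that term. Among the lists, the median term was -0.416 for monocyte genes, -1.145 for MHC class II presentation, -0.989 for dendritic cell markers, -0.285 for inflammatory cytokines and chemokines, -0.364 for neutrophil markers, -0.146 for GM-CSF and TGF-β signalling and 0.141 for lysosome genes. It was -0.333 for cell cycle genes (-0.168 without knockout day 11 replicate 2), -1.34 for interferon response genes (-0.182 without knockout day 2 replicate 1 and -2.267 without replicate 2), -0.208 for complement genes (-0.081 without knockout day 2 replicate 1), -0.147 for B cell markers (-0.081 without knockout day 11 replicate 1) and -0.061 for macrophage genes of other tissues (-0.093, -0.034 and -0.030 without knockout day 2, control day 11 and knockout day 11 replicate 1). Terms that lost their call without single arrays were those of 4 lists. Fatty acid oxidation (0.199) lost it without control day 2 replicate 1, knockout day 2 replicate 1 (0.097, adjusted p = 0.179), control day 11 replicate 2 or knockout day 11 replicate 1 (0.097). Mast cell and basophil markers (-0.084) lost it without the same 4 arrays (adjusted p from 0.0952 to 0.119) and came to -0.174, -0.133 and -0.144 without knockout day 2 replicate 2, control day 11 replicate 1 and knockout day 11 replicate 2. Alveolar epithelial markers (-0.11) lost it without knockout day 2 replicate 2 (-0.002) or control day 11 replicate 2 (-0.045) and came to -0.228 without knockout day 2 replicate 1. Endothelial markers (-0.161) lost it without control day 2 replicate 1 (-0.105, adjusted p = 0.0546) and came to -0.06 without knockout day 2 replicate 2 and -0.103 without control day 11 replicate 1. With arrays of one sex left out, complement, GM-CSF and TGF-β signalling, B cell markers, fatty acid oxidation and mast cell and basophil markers lost their calls. The sex covariate ended those of fatty acid oxidation and of mast cell and basophil markers, and leaving out dim genes those of fatty acid oxidation and B cell markers. With an estimated correlation none of the 16 lists was called.

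Single genes with such a difference were Fabp1 (-3.747), Ifitm6 (-3.622), Cd209a (-3.587), Clec4a1 (-3.372), Ccl17 (-3.346), Ifitm3 (-3.319), H2-Ab1 (-3.294) and Plac8 (-3.272), and with a positive term Fstl1 (3.147), Car6 (2.694), Ecm1 (2.474), the brain-type fatty acid binding protein gene Fabp7 (2.078), Phlda3 (1.886), the fatty acid elongase gene Elovl7 (1.882), the transcription factor gene Mkx (1.809) and the secreted kinase gene Fam20c (1.706). Fabp7 was 7.59 and 7.82 in controls and knockouts at day 2 and 6.34 and 8.65 at day 11. Calls lost without single arrays were those of H2-Ab1, given above, of Ifitm3 without any control array or knockout day 11 replicate 2 (adjusted p from 0.0876 to 0.13), of Fam20c without any array other than control day 11 replicate 2 (0.0517 to 0.136), of Mkx without any control array or knockout day 2 replicate 1 (0.0542 to 0.105), and of Phlda3 without either day 2 control or control day 11 replicate 1 (0.0502 to 0.068). A signal also appeared in probe sets without a single gene symbol, which the comparisons of genes do not use. Of 7715, 731 were called at day 2 (276 higher and 455 lower in knockouts, 9.5% against 17.9% of the named probe sets) and 650 at day 11 (274 and 376, 8.4% against 17.1%).

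The first pattern weighed is the rise of monocyte, MHC class II and dendritic cell genes in the knockouts at day 2. The interferon-high pool, as the whole cause, is argued against, since without it the 3 lists kept at least 0.82 of their median. Dendritic cells inside the day 2 knockout gate cannot be told apart from the same genes expressed by the sorted macrophages, because the rise of 12 of 19 dendritic cell markers is itself part of the pattern and no label gives the share of such cells. The markers with the highest signal in the day 2 knockouts were Cd24a (11.1 in the controls of that age and 11.6 in the knockouts), Ccl17 (8.58 and 9.74), Cd209a (5.42 and 9.22), Irf4 (4.73 and 8.77) and Epsti1 (6.79 and 8.55), levels of different probe sets not being comparable with each other. Of that list, 6 genes also stand in other lists. Genotype was not tested apart from the gate. The day 2 sort took F4/80+ cells, and how many dendritic cells that gate removed is not given.

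The second pattern is the interferon response in knockout day 2 replicate 1, in which 28 of 33 interferon genes were at least 2-fold higher than in replicate 2, among 135 genes in all. Cells of the 10 other types, as a much larger share of that pool than of replicate 2, are argued against. At most 5.9 percent of the markers of any of their lists were raised as much. A small share of such cells need not raise its markers 2-fold, so the test does not exclude it. Monocytes and macrophages of other tissues, with 7.4 and 9.4 percent of their genes raised as much, were not part of that test and stay open. Sex of the pooled mice is argued against as the whole cause, because 30 of the 33 genes differed by more than Xist did (0.83). A gene made only by the female mice would differ by no more than Xist, if the Xist signal is not compressed. Compression of that signal, 10.68 in replicate 1 and 9.85 in replicate 2, was not tested. No biological explanation was tested, since no label separates the 2 pools.

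The third pattern is the Pparg signal, little lower in knockouts at day 2 (-0.305) and not lower at day 11. An array under the wrong genotype is argued against, because the lowest control and the highest knockout median of the PPAR target list lay 0.602 apart, against at most 0.111 between arrays of a group. Undeleted cells like those of the controls, as the whole cause, are argued against as well. With them no gene would keep a smaller share of its control level than Pparg (0.809 at day 2 and 1.14 at day 11), and 13 of 33 PPAR target genes did at day 2 and 16 at day 11, with 95 percent intervals apart. Probes outside the deleted part could leave such a signal, and this cannot be told apart from undeleted cells that make little of these targets, because the probe positions are not given in the sources used here. The fold of Pparg therefore gives no measure of how complete the deletion was.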

How the results depend on the processing

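A covariate for the signal of Y-linked genes, the leaving out of arrays of one sex and the split of the day 11 controls were chosen after the data were seen. Of 468 called values of named genes, 310 kept their call in every setting and 0 changed sign. With a 2-fold threshold, which by construction counts fewer genes, the counts were 695 and 648 for genotype at days 2 and 11, 148 and 370 for age in controls and knockouts, 232 for the interaction, 726 for day 11 knockouts against day 2 controls, and 363, 61 and 77 for the overlaps of genotype, of age, and of control age with day 11 genotype. With arrays of one sex left out, which leaves 5 arrays, they were 2044 (genotype, day 2), 525 and 1090 (age), 222 (interaction) and 2733 (day 11 knockouts against day 2 controls), and the overlaps 1348, 232 and 218. With the 2 day 11 controls split, 1 for each comparison, the overlap of control age with day 11 genotype was 145 or 113, each comparison having lost an array. With arrays of one sex left out sex-linked genes turned to 1.2 at day 2 and -1.173 in the interaction, and Pparg at day 2 was -0.15 (adjusted p = 0.421). It was -0.242 (0.0612) with the covariate and -0.305 (0.0944) with only the 2 groups fitted. The covariate gave 1463 genes for age in knockouts and 401 for the interaction. Array weights gave 1496 and fitting only the 2 groups 1581 genes for age in controls, and the latter 1466 for age in knockouts. With only the 2 groups fitted, the order of the 2 age counts thus turned around. The weights were equal within each group, 1.144 and 1.134 in controls at days 2 and 11 and 0.81 and 0.952 in knockouts. They could therefore mark out no single array, and only let controls count with a smaller spread than knockouts. For the shift with the covariate the cause was not tested. Of the 30 lists, 23, 13, 8, 20 and 16 were called, and with an estimated correlation 1 at day 2 and 0 in the 4 other contrasts. Fry called 21, 16, 4, 16 and 7 lists. It did not call interferon response (fry adjusted p = 0.131) or glycolysis (0.188) at day 2, both called by camera. Nor did it call cell cycle in the interaction (fry adjusted p = 0.183). Leaving out dim genes, which takes away 8092 genes, left 5 lists for age in controls. Taking the replicate number as a block changed little (3692, 3415, 975, 2823, 558 and 4672 genes), quantile normalization once more and centring on the median less. Leaving out 1 array at a time gave ranges of 2223 to 3605 and 2059 to 3760 (genotype), 233 to 1292 and 1541 to 2985 (age), 197 to 942 (interaction), 2948 to 5063 (day 11 knockouts against day 2 controls), -0.40 to -0.21 (Pparg at day 2) and 1437 to 1941, 136 to 657 and 106 to 455 (overlaps). Signal over background limits the dimmest genes, and background was not measured here.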

Other observations

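The genes in this part that stand in no list were chosen after their values were seen. Of the 45 genes called in both genotype comparisons with opposite signs, 33 were higher in knockouts at day 2 and lower at day 11, and 12 the reverse. Csf3r, the G-CSF receptor gene of neutrophils and monocytes, was higher by 1.29 at day 2 and lower by -1.27 at day 11, Cd300e, a receptor of monocytes, went from 1.69 to -1.10, and Chst15, a sulfotransferase, from 0.51 to -2.12. Ccl22 went from 0.97 to -0.88 beside Ccl17 (1.16 and -2.19), both ligands of the receptor CCR4. Prickle2, a planar polarity gene, went the other way, from -0.72 to 0.89. The knockouts of both ages held high Csf1 (2.66 at day 2) and Kcnn4, a calcium-activated potassium channel gene (3.84 and 3.91).

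With age in knockouts, 13 of 32 macrophage genes of other tissues fell and 2, Mertk and Trem2, rose (14 and 3 adjusted over the list alone, camera adjusted p = 0.000268, and adjusted p = 0.24 with an estimated correlation). Inflammatory genes fell in 10 of 39 cases, Vegfa by 1.71 ± 0.20, and Il6 rose (13 and 1 adjusted over the list alone, camera adjusted p = 0.000167, and adjusted p = 0.316 with an estimated correlation). Of the 33 PPAR target and lipid droplet genes 11 rose and 4, Lipe, Dgat1, Dgat2 and Cyp27a1, fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.278 with an estimated correlation). Cideb, a relative of Cidec, rose by 1.18 ± 0.18 and Mgll, monoacylglycerol lipase, by 1.65 ± 0.24.

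Genes outside the interferon list also set knockout day 2 replicate 1 apart from replicate 2. Nos2, inducible nitric oxide synthase, was 4.99 higher on the log2 scale, Saa3 3.66 and the chemokine gene Cxcl9 3.42, beside Rsad2 (5.22) and Ifit3 (4.88) of the list. Xist was 3.38 in control day 2 replicate 2 and 3.46 in knockout day 11 replicate 1, near the floor, and Eif2s3y, a Y-linked gene, was 4.05 in knockout day 2 replicate 1, so the pools differed in the sex of their mice. Replicates of the day 2 knockouts differed by at least 2-fold in 142 genes, of the day 11 knockouts in 65, of the day 2 controls in 19 and of the day 11 controls in 2.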
